A study of Mus musculus with 18 samples.

How the data were processed

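Total RNA from mouse hearts was, per the labels, isolated with Trizol and an RNeasy column, copied into cDNA from an oligo(dT) primer with Cy3- or Cy5-labelled dUTP, and hybridised to spotted oligonucleotide arrays. Each array compared 1 wild-type with 1 Taut knockout heart of the same age, in 5 pairs of young and 4 pairs of old mice. Separate mice were used for each pair, and pair numbers carry no link between the ages that the labels state. The 18 columns of values are the 2 grids of the 9 arrays.

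According to the labels, the authors normalized each channel on its own, globally, on the signals left after setting aside 20% at either end. The deposited values are in log2: they lie around 0, and 2 raised to the value is a whole number of hundredths for 99.9% of 10492 values (tolerance 0.02 hundredths). The ratios run from 0.01 to 100, with 14 values at these ends, and 176 values (1.68%) are exactly 0. Scanner, background correction and spot filters are not given in the sources used here, nor are intensities, so dim and bright spots could not be told apart. The values were used as deposited, without another centring. The numerator of the ratio is not stated. The rule set beforehand checked the reading by correlating pairs of the same and of opposite dye orientation over all genes, and by Slc6a6. Neither settled it, and for that case the rule gives signs and sizes without a direction. The reading as Cy5 to Cy3 is shown beside them.

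Of 768 features 584 had values, of which 528 had a gene symbol, covering 219 genes, and 56 had none. Symbols were matched by Entrez Gene identifier to a RefSeq gene table, which changed none of them. Spots with the same symbol were averaged within a grid, and the 2 grids were averaged within an array, so that each pair counted once. Genes with a value in at least 3 pairs of each age were kept, which left 218 and excluded A1bg, which had no value in young pairs. Casp8 and Icam1 were each represented by 2 sequence accessions, which were averaged.

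All comparisons came from 1 linear model fitted with limma 3.58.1 in R 4.3.3 on the 9 pairs, with a mean for each age and 1 coefficient for the dye of the knockout heart (6 residual degrees of freedom, 13.5 with limma's prior). The young mean, the old mean, the average of both and their difference (old minus young) were tested with moderated statistics, two-sided, and adjusted by the Benjamini-Hochberg method over 218 genes, with a threshold of 0.05. Errors are standard errors from this fit unless stated otherwise. Gene lists and markers of other cell types were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, and adjusted over the 21 lists with at least 3 measured genes (18 gene lists and 3 lists of cell type markers). The lists of oxidative phosphorylation (2 measured genes), skeletal muscle markers (2) and atrial markers (1) were too small, and no gene of the cell cycle list or of the smooth muscle, leukocyte, lymphocyte, erythroid and adipocyte markers was measured. Overlapping lists share genes: Acta1 and Myh7 are in both the hypertrophy and the contractile list. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

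The model, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Slc6a6 and, for young, old and the mean of both ages, the genes past the threshold with 1 sign in every pair, up to 10 on each side. With fewer than 10 of these, it was filled to 5 on each side by the smallest p, said not to pass where they did not. It also names the 2 genes of each list with the smallest p in the mean of both ages, and the 5 genes with the smallest p for the difference between ages. The 12 genes called in the mean of both ages are all named, of which Angpt1, Sp1, Ankrd1 and Fn1 come in through the young pairs or their lists, not through the first part of the rule in the mean.

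Alternatives were a fit without the dye term, a fit of each age alone, a dye coefficient for each age, centring and scaling of each array, each grid alone, all grids with the array as a random block, other filters on missing or noisy genes, single spots, robust regression, robust empirical Bayes, array weights, the other reading of the ratios, a block on pair number, and leaving out each pair in turn. After the data were seen 3 were added: the dye coefficient turned in the old pairs, values of 0 or at the ends of the scale left out, and old pair 1 and young pair 5 left out together. The procedure was tested on simulated data (20 simulations, 40 changed genes of 218). It called 56.8%, 50.0% and 90.7% of changes of 0.6 on the log2 scale in young, old and the mean of both ages, and 18.2% of changes of that size between the ages, with 1.1 to 1.6 false calls per simulation. A shift of 0.4 on the log2 scale given to the 9 matrix genes in young pairs was called in 20 of 20 simulations, and in 0 without the shift, while other lists were called 13 times in all. The simulated genes varied independently of each other, with 1 dye coefficient for both ages. With 40 changed genes the adjusted threshold is easier to pass than with few, so the shares called may be too high for comparisons with few changes. In the data the matrix genes had an estimated correlation of 0.29, so the simulated rates for lists do not carry over to the real list tests.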

Results

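Hearts of mice lacking the taurine transporter (Taut, encoded by Slc6a6) were compared with hearts of wild-type mice on spotted oligonucleotide arrays read in Cy3 and Cy5. Taurine is an amino sulphonic acid that heart muscle takes up through this transporter and holds at a high concentration. Each array carried labelled cDNA from 1 wild-type and 1 knockout heart, so that 1 array gave 1 mouse pair. There were 5 pairs at 2 months of age (young) and 4 pairs at 15 to 16 months (old). The knockout heart was labelled with Cy5 in young pairs 1, 3 and 5 and old pairs 1 and 3, and with Cy3 in the other 4 pairs. Every array was printed as 2 grids with 2 spots per oligonucleotide in each grid, and 218 named genes had values in enough pairs of both ages to be tested. Over genes, which are not independent replicates, the grids of an array correlated with r between 0.27 (young pair 5) and 0.80 (young pair 4). The median log2 ratio of an array ran from −0.25 (old pair 1) to 0.39 (old pair 4). Signal intensities are not given in the sources used here, so the level of a gene above background is unknown, and the number of arrays limits the precision.

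The deposited value was read as a log2 ratio between the genotypes of a pair, and which genotype is the numerator is not stated. Nppa had a positive value in all 9 pairs whichever dye the knockout heart carried. In a ratio of Cy5 to Cy3 that would be a fixed dye bias of the gene, which these values cannot exclude. Over genes, arrays of 1 age correlated with a median r of 0.43 for the same dye orientation and 0.22 for opposite orientations. Between the ages the medians were 0.26 and 0.36, so this check did not settle the reading. Signs are therefore given as deposited, and a gene is described by its side (positive or negative) and by the size of the difference, not as higher or lower in the knockout heart.

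The first comparison asked which cardiac transcripts differed between Taut-deficient and wild-type hearts on average over both ages. Slc6a6 (Entrez Gene 21366), the gene that was knocked out, had a mean log2 ratio of 0.59 ± 0.12 (SE, n = 9 pairs), which is a 1.51-fold difference (adjusted p = 0.0154, limma). Its value was positive in 8 of 9 pairs and was −0.048 in young pair 2. The call was lost without young pair 3, without old pair 2 and on grid 2 alone. Nppa (Entrez Gene 230899), which encodes atrial natriuretic peptide, had the largest difference of the 218 genes, at 7.55-fold (log2 ratio 2.92 ± 0.25, n = 9, adjusted p = 4.23e-06), and was positive in all 9 pairs. Nppa was also the only atrial marker measured, so a difference in atrial tissue between the heart samples was not tested. Acta1 (Entrez Gene 11459), the skeletal muscle alpha-actin, lay on the opposite side with a 4.6-fold difference (log2 ratio −2.20 ± 0.37, n = 9, adjusted p = 0.00437). It was negative in 8 of 9 pairs, from −4.85 to −1.51, and positive in old pair 4 (0.80).

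In all, 12 of 218 genes passed an adjusted p of 0.05, 9 of them on the positive and 3 on the negative side. At an unadjusted p under 0.05 there were 40 genes (24 positive, 16 negative), against 10.9 expected by chance. Slc38a2 and Slc38a4, which encode sodium-coupled neutral amino acid transporters, lay on the side of Slc6a6 with differences of 1.60-fold (log2 ratio 0.67 ± 0.13, adjusted p = 0.0148) and 1.5-fold (0.59 ± 0.12, adjusted p = 0.0157). Slc38a2 was positive in all 9 pairs and Slc38a4 in 8 of 9. Slc38a3, of the same family, had a negative ratio of −0.47 ± 0.14 and did not pass (adjusted p = 0.0756). On the positive side also stood Ankrd1, a cardiac ankyrin repeat protein of the hypertrophy programme (0.76 ± 0.20, adjusted p = 0.0394), and Angpt1, the angiopoietin ligand of the endothelial receptor Tek (0.64 ± 0.16, adjusted p = 0.0318). The transcription factor Sp1 (0.63 ± 0.14, but 1.02 on grid 1 and 0.24 on grid 2), the matrix glycoprotein Fn1 (0.61 ± 0.16) and the lysosomal protease Ctsh (0.53 ± 0.14, positive in all 9 pairs) completed that side, with adjusted p values of 0.0179, 0.0408 and 0.0394. Besides Acta1, the negative side held Etfdh, which passes electrons from mitochondrial fatty acid oxidation to ubiquinone (−0.57 ± 0.13, negative in all 9 pairs), and the quinone reductase Nqo1 (−0.51 ± 0.12, negative in 8 of 9), both with an adjusted p of 0.0179. The genes Nppa, Slc38a2, Ctsh and Etfdh passed and had 1 sign in every pair. Hspd1, the mitochondrial chaperonin, had a negative ratio and did not pass (−0.40 ± 0.13, adjusted p = 0.136). The count was 3 without young pair 3, 5 without old pair 1 and 6 without old pair 2, 2 on grid 2 alone, 4 without both arrays whose grids correlated least (old pair 1 and young pair 5), 19 of 582 for single spots and 24 with robust regression. If the values were a Cy5 to Cy3 ratio, 0 genes would pass in limma (14 at an unadjusted p under 0.05).

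**Figure D1:**
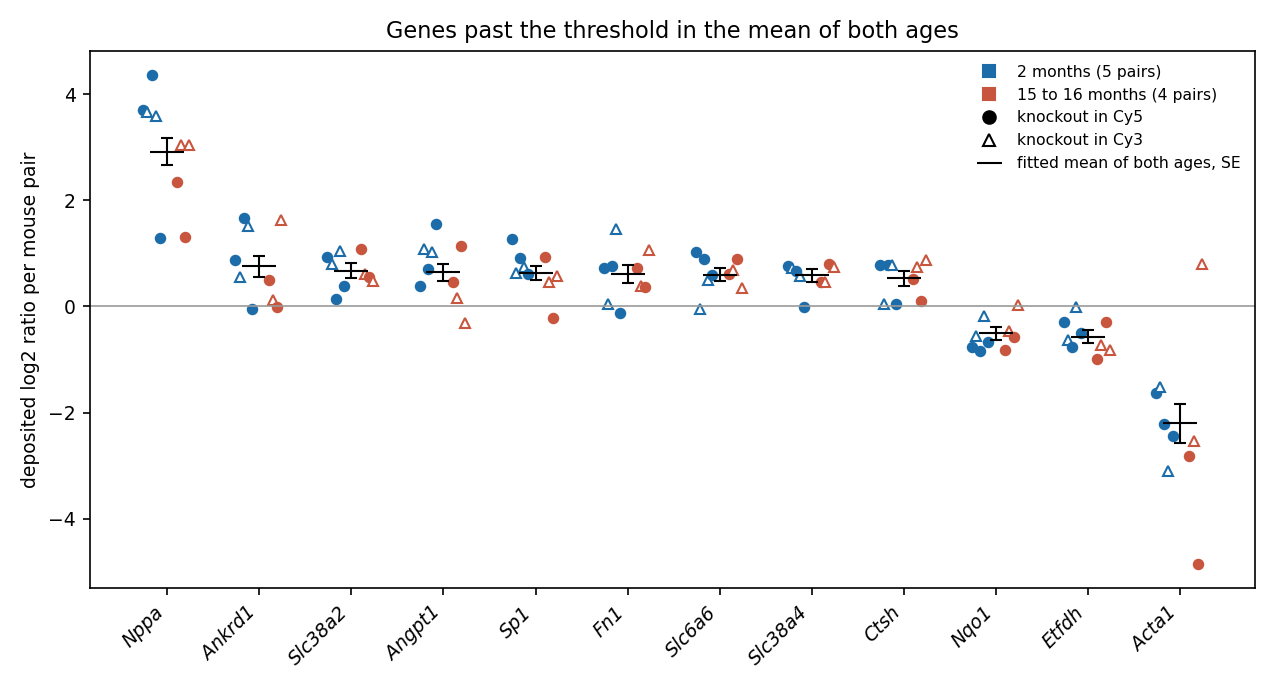
Deposited log2 ratio (y axis) of each mouse pair for the 12 genes with an adjusted p under 0.05 in the mean of both ages (x axis). Points are single pairs, coloured by age with the dye of the knockout heart as the symbol, and the black bar is the fitted mean of both ages with its SE; Nppa is positive in all 9 pairs and Acta1 is negative in all but old pair 4 (0.80).

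Grouped by the gene lists that were fixed before the data were examined, the cardiac hypertrophy and fetal gene programme held the largest differences, with 3 of its 4 measured members past the threshold over all genes and 3 when adjusted over the list alone. Nppa and Ankrd1 were positive and Acta1 negative, although Nppa and Acta1 are both known as fetal genes that hypertrophied hearts express again. Myh7, the slow myosin heavy chain of the same programme, had 0.26 ± 0.18 and did not pass. Its value was 0.087 without old pair 1 and 0.41 without old pair 3. The list as a whole did not stand apart from the other genes (camera adjusted p = 0.381). Among 9 genes of osmotic stress and organic osmolytes, 2 passed (Slc38a2 and Slc38a4, also when adjusted over the list alone) and 7 did not (adjusted p of the list = 0.680). Of 6 genes of taurine transport and synthesis only Slc6a6 passed, over all genes and when adjusted over the list alone (adjusted p of the list = 0.526). Csad, which makes hypotaurine, the precursor of taurine, had a ratio of 0.30 ± 0.14.

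All 9 measured genes of extracellular matrix and fibrosis had a positive mean ratio, averaging 0.29 (adjusted p of the list = 0.115). Fn1 passed over all genes, and Fn1 and Timp2 (0.35 ± 0.12), an inhibitor of matrix metalloproteinases, when adjusted over the list alone. The 5 fibroblast markers, 4 of which are also in that list, were positive as well, averaging 0.36 (adjusted p = 0.115), with Fn1 alone called. Col1a2 had 0.35 ± 0.16, and 0.20 ± 0.15 without old pair 4. Markers of endothelial cells averaged −0.0039 over 7 genes (adjusted p = 0.685; Kdr −0.22 ± 0.14, Tek 0.17 ± 0.13). Markers of cardiomyocytes averaged −0.081 over 4 genes (adjusted p = 0.526), with myoglobin (Mb) at −0.35 ± 0.15. All 3 cathepsins that made up the protein degradation list were positive, and Ctsh was called (adjusted p of the list = 0.263). Ctsb had 0.37 ± 0.17, and 0.18 ± 0.16 without old pair 4. The 5 heat shock proteins and chaperones were all negative, averaging −0.18, with Hspd1 and its partner Hspe1 (−0.30 ± 0.14) the farthest from 0, and none was called (adjusted p of the list = 0.261). These signs held after centring and after scaling of each array.

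The remaining lists held at most 1 called gene each, and none stood apart from the other genes. In growth factor and insulin signalling, Angpt1 was called among 12 genes (adjusted p of the list = 0.526), and Insr, the insulin receptor, had −0.31 ± 0.11 and a negative value in all 9 pairs. In oxidative stress and glutathione, Nqo1 was called among 14 genes (adjusted p = 0.526), and Ncf1, a subunit of the phagocyte oxidase, had 0.22 ± 0.12. Acta1 was the only call among 4 contractile genes, whose median (0.037) and mean (−0.47) differed in sign (adjusted p = 0.526). Of 4 genes of fatty acid metabolism, Fabp5, a fatty acid binding protein (0.36 ± 0.12), passed when adjusted over the list alone, and Hadha, of mitochondrial beta-oxidation, had −0.36 ± 0.16 (adjusted p of the list = 0.526). Of 5 genes of renin, angiotensin and adrenergic signalling (adjusted p of the list = 0.526), Prkg1, the cyclic GMP-dependent protein kinase (0.52 ± 0.15, adjusted p over all genes = 0.0756), passed when adjusted over the list alone. Npr1, the receptor of atrial natriuretic peptide, had 0.33 ± 0.15, but 0.59 on grid 1 alone and 0.079 on grid 2 alone. Without a call stood calcium handling (5 genes, adjusted p = 0.685; Ryr2 0.27 ± 0.12, Pln −0.24 ± 0.13), the unfolded protein response (3 genes, 0.685; Xbp1 0.22 ± 0.12, Atf3 −0.20 ± 0.15), glucose metabolism (5 genes, 0.526; G6pc 0.10 ± 0.13) and apoptosis (10 genes, 0.685; Diablo −0.31 ± 0.12, Fas 0.19 ± 0.12). The same held for inflammation (12 genes, 0.685; Il10 −0.73 ± 0.26, Il1r1 0.35 ± 0.15), immediate early genes (7 genes, 0.526; Jun −0.19 ± 0.15) and reference genes (5 genes, 0.993; Ppia 0.45 ± 0.16, Odc1 −0.33 ± 0.14). Without old pair 1 the mean of both ages for Il10 was −0.42 ± 0.19. The lists of osmolytes and reference genes had a negative median and a positive mean, and endothelial markers a positive median with a mean just under 0. In fry's mixed test, which asks whether any members differ in either direction, 6 lists passed: growth factors (adjusted p = 0.0155), osmolytes (0.0155), hypertrophy (0.0269), and the taurine, fatty acid and renin lists (0.0425 each). For a shift in 1 direction 0 lists passed, by camera with the preset correlation (3 at an unadjusted p under 0.05), by camera with an estimated correlation (0) or by fry (3).

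The second comparison asked what differed between the genotypes in young hearts, at 2 months. Nppa differed 10.5-fold (log2 ratio 3.40 ± 0.33, n = 5 pairs, adjusted p = 2.36e-05, limma) and was positive in 5 of 5 pairs, from 1.28 to 4.35. It was the only 1 of 218 genes to pass, and 26 genes (21 positive, 5 negative) had an unadjusted p under 0.05. Slc6a6 had 0.55 ± 0.16 (4 of 5 pairs positive) and did not pass (adjusted p = 0.124). The nearest genes below the threshold were Sp1 (0.82 ± 0.19) and Angpt1 (0.92 ± 0.21), each positive in 5 of 5 pairs with an adjusted p of 0.0552, and Acta1 (−2.05 ± 0.49, negative in 5 of 5, adjusted p = 0.0580). Slc38a2 (0.67 ± 0.18), Ankrd1 (0.96 ± 0.27) and Nqo1 (−0.56 ± 0.15) each had an adjusted p of 0.0955. Odc1, which makes putrescine, had −0.59 ± 0.19 (adjusted p = 0.147), Slc38a3 −0.53 ± 0.19 (0.250) and Etfdh −0.43 ± 0.17 (0.324), all 3 negative in 5 of 5 pairs.

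Genes of extracellular matrix lay together on the positive side in the young pairs: all 9 had a positive ratio, averaging 0.39 (camera adjusted p = 0.0333), and 8 of 9 after centring each array. The 5 fibroblast markers averaged 0.52 and were all positive (adjusted p = 0.0333). Neither call held with an estimated correlation (adjusted p = 0.922 for both) or in fry (adjusted p = 0.241 for both). Within these lists Timp2 had 0.51 ± 0.16, Fn1 0.59 ± 0.22 and Col1a2 0.52 ± 0.22. Fn1 was 0.33 ± 0.23 without young pair 4, and Col1a2 was 0.79 ± 0.22 without young pair 2. Adjusted over the list alone, 0 of the 9 matrix genes passed in limma (5 had an unadjusted p under 0.05). Among the 5 fibroblast markers 2 passed in that way, Fn1 and the fibrillar collagen Col3a1 (0.70 ± 0.26, a gene named after its value was seen). The hypertrophy list had 3 calls when adjusted over the list alone (Nppa, Ankrd1 and Acta1), the osmolyte list 2 (Slc38a2 and Slc38a4), and the taurine, contractile, oxidative stress, growth factor and reference lists 1 each (Slc6a6, Acta1, Nqo1, Angpt1 and Odc1). Among the 21 lists, no other had a camera adjusted p under 0.458. The count of genes was 14 when the young pairs were fitted alone, 8 with a dye coefficient for each age, 16 with array weights and 14 with robust regression, and 4 without old pair 3. Both lists fell short of the threshold without young pair 1, 3 or 4, and the matrix list also without young pair 2 or without the dye term.

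The third comparison asked the same of old hearts, at 15 to 16 months. Nppa differed 5.41-fold (log2 ratio 2.44 ± 0.37, n = 4 pairs, adjusted p = 0.00319, limma) and was positive in 4 of 4 pairs. It alone passed of 218 genes, and 23 genes (11 positive, 12 negative) had an unadjusted p under 0.05. Slc6a6 had 0.64 ± 0.18, positive in 4 of 4 pairs, and did not pass (adjusted p = 0.154). Acta1 had −2.35 ± 0.55 (adjusted p = 0.0867), negative in 3 of 4 pairs, and its size rests on single pairs: it was −1.61 ± 0.50 without old pair 3 and −3.35 ± 0.41 without old pair 4, where it passed (adjusted p = 0.00103). Also short of the threshold were Slc38a2 (0.68 ± 0.20) and Slc38a4 (0.62 ± 0.18), each positive in 4 of 4 pairs with an adjusted p of 0.154. The ATP-binding cassette transporter Abcc6 had 0.54 ± 0.18 (adjusted p = 0.215). On the negative side were the cytokine Il10 (−1.47 ± 0.38, adjusted p = 0.132, −3.99 in old pair 1), Etfdh (−0.71 ± 0.19, 0.132), the bile acid transporter Slc10a1 (−0.82 ± 0.25, 0.154) and Hspd1 (−0.59 ± 0.20, 0.215), each negative in 4 of 4 pairs. The 5 heat shock proteins and chaperones were all negative, averaging −0.36, the smallest camera adjusted p of the 21 lists at this age (0.184). Adjusted over the list alone, Hspd1 passed among them, Il10 in inflammation, Slc6a6 in the taurine list and Nppa and Acta1 in hypertrophy. The contractile list held 1 such call (Acta1) and the osmolyte list 3: Slc38a2, Slc38a4 and Slc5a3, the myo-inositol transporter (−0.92 ± 0.32, named after its value was seen). Old pair 1 carried much of these negative values: without it Il10 had −0.81, Slc10a1 −0.38, Hspd1 −0.39 and Slc5a3 −0.35. On grid 2 alone Il10 had −0.94, Slc10a1 −0.47 and Slc5a3 −0.18. The 9 matrix genes averaged 0.19, with 8 positive, and the 5 fibroblast markers 0.19, with 4 positive (adjusted p = 0.398 and 0.429). By camera, 0 lists passed and 1 had an unadjusted p under 0.05, and in fry 0 passed and 0 had one. The call of Nppa was lost without old pair 2 (adjusted p = 0.0521). The count was 6 with the old pairs fitted alone, 11 with robust regression and 3 without old pair 3.

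The fourth comparison asked whether the difference between the genotypes itself changed with age. No gene passed in limma (0 of 218, smallest adjusted p = 0.971), and 2 had an unadjusted p under 0.05. The difference in log2 ratio (old minus young) was −0.96 ± 0.50 for Nppa, −0.30 ± 0.74 for Acta1 and 0.087 ± 0.24 for Slc6a6, and none of these passed. The sign for Acta1 rests on old pair 3, without which it was 0.51 ± 0.64, and that for Slc6a6 was negative without young pair 2 or old pair 2. The 5 smallest p values, none of which passed, were those of Il10 (−1.49 ± 0.51), the transporter Abcc2 (0.72 ± 0.28), the nucleoside diphosphate kinase Nme1 (0.61 ± 0.29), the aquaglyceroporin Aqp9 (1.14 ± 0.54) and Slc10a1 (−0.71 ± 0.34). Single arrays carried 3 of them: without old pair 1 Il10 had −0.77 and Slc10a1 −0.23, and without old pair 2 Aqp9 had 0.49. The same 3 genes also differed between the grids of the arrays. On grid 1 alone Il10 had −2.42, Slc10a1 −1.08 and Aqp9 0.0012. On grid 2 alone they had −0.57, −0.34 and 2.28. Nme1 had 0.40 without young pair 2. Among the 21 lists the smallest camera adjusted p was 0.595, shared by the heat shock list, and 1 list had an unadjusted p under 0.05, while in fry 0 passed and 0 had one. The matrix list differed by −0.20 between the ages (adjusted p = 0.804), so a difference between them was neither shown nor excluded. The median 95% half-width of a gene's difference, unadjusted, was 0.60. In simulated data 18.2% of changes of 0.6 between the ages and 60.8% of changes of 1 were called. The median over all genes was −0.13, and centring each array moved every gene's difference by 0.11.

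**Figure D2:**
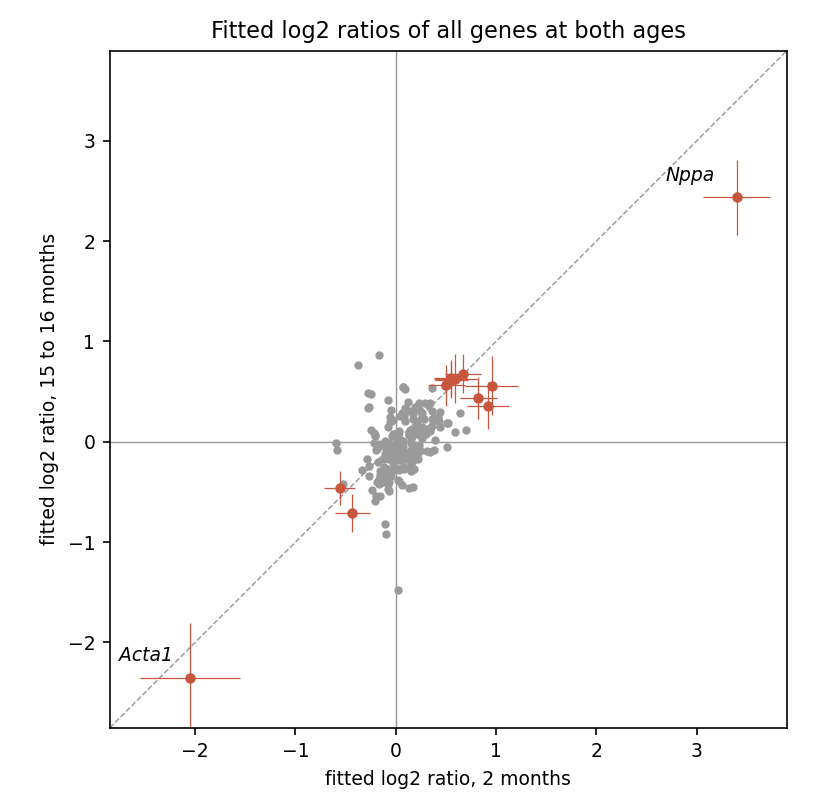
Fitted log2 ratio at 15 to 16 months (y axis) against that at 2 months (x axis) for 218 genes, with the dashed line where both are equal. Red points with SE bars are the 12 genes past the threshold in the mean of both ages, and 145 genes, those at the upper right and lower left of the zero lines, have the same sign at both ages.

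Over genes, which are not independent replicates, the young and old log2 ratios correlated with Pearson's r of 0.68 and Spearman's rho of 0.50. Without Nppa and Acta1, r was 0.45 and rho 0.48. The sign was the same at both ages for 145 of 218 genes. Nppa, Slc38a2, Ctsh, Etfdh, Insr and Slc10a1 had 1 sign in all 9 pairs, 6 genes against 0.852 expected by chance, and 0 genes had 1 sign in every young pair and the other in every old pair.

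**Figure D3:**
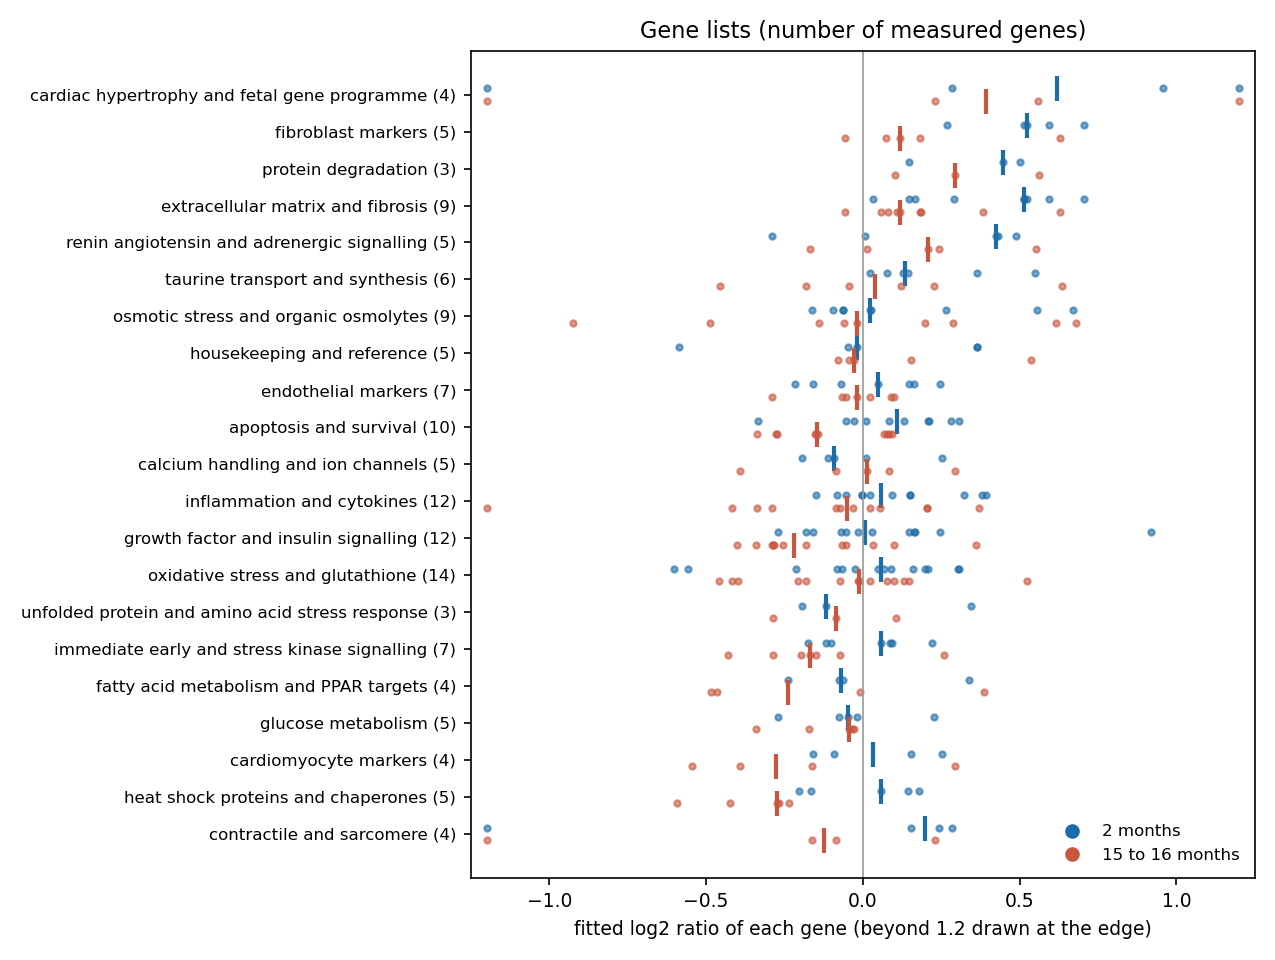
Fitted log2 ratio (x axis) of each measured gene in the 21 lists (y axis, number of measured genes in brackets) at 2 months (blue) and 15 to 16 months (red). Points are genes, those beyond the axis are drawn at its edge, and vertical bars are list medians; the 9 matrix genes are all positive at 2 months and the 5 heat shock genes all negative at 15 to 16 months.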

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

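The tests of other splits of the pairs were set before the results were seen; the tests on Acta1 in old pair 4, on the sign of Slc6a6 and on the ABC transporters were chosen only after their results were seen, as was the comparison of dye coefficients between ages.

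The 7 single pairs that stood far from the others of their age came from 94 groups of pairs tested, of which 4.7 would stand out by chance. Nppa of young pair 5 was 1.28, against 3.58 to 4.35 in the other young pairs. Slc38a4 of the same array was −0.0096, against 0.58 to 0.77. On young pair 2, Npr1 was −0.21 against 0.49 to 0.68, and Ryr2 was 0.54 against 0.081 to 0.21. On young pair 3, Xbp1 was 0.13 against 0.36 to 0.42, and Slc10a1 was −0.44 against −0.13 to −0.029. Slc10a1 of old pair 1 was −2.21, against −0.50 to −0.22 in the other old pairs.

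The coefficient of the knockout heart's dye differed between the ages for 23 of 218 genes (59 at an unadjusted p under 0.05), led by the metallothionein Mt1 (0.93 in young and −0.93 in old pairs), Gapdh (0.83 and −0.45) and Hmox1 (0.66 and −0.86), which were named after their values were seen. Over genes, the dye coefficients of the ages correlated with r = −0.28, while the model has 1 dye coefficient for both ages. The sum of both coefficients passed for 0 genes in limma (14 at an unadjusted p under 0.05). With the dye coefficient turned in the old pairs, the count was 7 in young pairs, 1 in old pairs and 15 in the mean of both ages. An exchange of the dye labels at 1 age could give these values, and so could ratios formed differently at the ages, and neither is settled by them. Genotypes turned in the ratios of 1 age would also turn the genotype means. Unless the genotype effect itself reversed, the means argue against that. They correlated between the ages with r = 0.68 (0.45 without Nppa and Acta1), and 145 of 218 genes kept their sign. Under the reading as Cy5 to Cy3, these coefficients would be the differences between genotypes. In limma 21 genes would then pass for the difference between ages. A feature without a gene name had 2 spots that passed when each spot was tested alone in the mean of both ages, at 0.98 (adjusted p = 0.0189) and 0.89 (adjusted p = 0.0215), the only 2 of 56 unnamed spots to do so.

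For the mean of both ages, chance is argued against as the source of the count of genes. Of 256 possible sign changes of the pairs, 98 were run and could be fitted. Among these, 12 genes were reached in 1, the real one, and the highest of the others had 10. Sign changes that were not run could reach more. The test also cannot tell a genotype effect from a fixed dye bias of the genes. For young pairs the 16 sign changes are too few for a share under 0.05. The real count was 1, 2 of 16 had as many, and the highest other was 18. That sign change turned young pairs 2 and 4, the ones with the knockout heart in Cy3. It therefore mostly tests the difference in dye coefficients between the ages given above, and is not a separate pattern. With a dye coefficient for each age the young count was 8. For old pairs the 8 sign changes are also too few. The real count was 1, 3 of 8 had as many, and the highest other was 11, for turning old pairs 2 and 4. These are again the ones with the knockout heart in Cy3, so the same holds. With a dye coefficient for each age the old count was 2. For the difference between ages the real count was 0, which every split reaches, so the 99 splits decide nothing about chance. The highest of the others had 24, with young pairs 2 and 4 and old pairs 1, 2 and 3 on 1 side. Apart from old pair 2, that split follows the knockout heart's dye in opposite ways at the ages. It therefore overlaps with the same difference in dye coefficients.

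Acta1 had a positive ratio in old pair 4 (0.80) and a negative one in the other 8 pairs (−4.85 to −1.51), and its mean over both ages without old pair 4 was −2.75 ± 0.26. An exchange of the wild-type and knockout hearts on that array is argued against by Nppa, which was 3.04 there and positive as in every other pair. A shift of the whole array is argued against because Acta1 remained at 0.41 after the array's median was taken off. A faulty spot or grid is argued against because all 4 spots were positive, the lowest at 0.50, while all 32 spots on the other arrays were negative. What stays open is a difference between the hearts or the tissue sampled, which with 1 mouse of each genotype on the array was not tested. Acta1 and Mb were the only skeletal muscle markers measured, so skeletal muscle in the samples was not tested either.

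The 6 genes of ATP-binding cassette transporters (Abcb11, Abcc1, Abcc2, Abcc3, Abcc5 and Abcc6) all had a higher log2 ratio in old than in young pairs, by 0.28 to 1.03 (mean 0.62, 0.74 after centring), although no single gene passed (adjusted p = 0.971), apart from Abcb11 when old pair 3, where it was −2.0 against 1.72 and 1.96 in old pairs 2 and 4, was left out. A single array is argued against as the whole source, since the mean difference was still 0.47 without old pair 2, where Abcc3 alone was 3.62, and lay between 0.47 and 0.85 over the 9 arrays left out in turn, although old pair 3 (mean −0.34 over the 6 genes) lay among the young pairs (−0.67 to 0.024). The position on the array may contribute, since 20 genes printed within 10 features of them differed by 0.18 ± 0.07 in the same direction. That error is an SE over the 20 genes, which share the same arrays, and holds no spread between mice. A contribution of position cannot be told apart from the genes' own difference. Abcb11 and Abcc3 are also among the 23 genes whose dye coefficient differed between the ages (−1.36 and −1.26 in old pairs). A genotype effect on these transporters that depends on age stays open too: over 20 families of genes with a shared symbol the adjusted p was 7.93e-08 by camera with a preset correlation and 0.0957 with an estimated correlation. Of their values 4 lie at the ends of the scale, and the family was picked because of its values, so this is a hypothesis. Without signal intensities, noise of signals near background was not tested as a source.

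The sign of Slc6a6 (0.59 in the mean of both ages) bears on which genotype is the numerator. If the oligonucleotide lay in a deleted or unstable part of the transcript, a positive ratio would be in line with wild type over knockout, in which case Nppa would be the transcript lower in knockout hearts and Acta1 the one higher. If the transcript remained and was raised in the absence of its product, the same 0.59 would be in line with knockout over wild type, with Nppa higher in the knockout. The position of the oligonucleotide relative to the deleted part is not given in the sources used here, so the readings cannot be told apart. A full loss of the transcript from the probed part was not seen under either reading, since the difference was 1.51-fold, although hybridisation to related transcripts or background could hide one.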

How the results depend on the processing

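Besides the alternatives fixed beforehand, 3 were chosen only after the data were seen: the dye coefficient turned in the old pairs, values of 0 or at the ends of the scale left out, and old pair 1 and young pair 5 left out together.

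The gene values of the text were recomputed in the comparison for which they are given: of 1964 values 1742 kept their sign and their side of the threshold, 72 of called genes no longer passed, 110 of uncalled genes passed and 40 changed sign. Of these, 37 changed under the reading as Cy5 to Cy3 and 3, all differences between the ages, on leaving out 1 pair: Acta1 (0.51 without old pair 3, down to −1.21 without old pair 4) and Slc6a6 (−0.047 without young pair 2 and −0.013 without old pair 2, up to 0.19 without old pair 1). The tallies that follow leave out the reading as Cy5 to Cy3, under which none of these genes was called. Nppa was called in the mean of both ages under all 25 other alternatives (log2 ratio 2.75 to 3.13) and in young pairs under all 26. In old pairs it was called under 25 of 26, the exception being without old pair 2 (adjusted p = 0.0521). Acta1 kept its call in the mean under all 25 (−2.75 to −1.87, adjusted p up to 0.0343). Slc38a2 and Slc38a4 kept theirs under 23 of 25, Slc6a6 under 21 of 24 (0.53 to 0.67, adjusted p 0.00420 to 0.109), Nqo1 under 20 of 25 and Etfdh under 19 of 25. Sp1 kept it under 17 of 24 (0.24 to 1.02, adjusted p up to 0.548, the ends being grid 2 and grid 1 alone), Ankrd1 under 16 of 25, Ctsh and Fn1 under 15 of 25 and Angpt1 under 14 of 25. On grid 2 alone only Nppa and Acta1 passed in the mean. Without a measure of signal over background, it is unknown how far dim spots limited these calls.

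Counts of genes were as follows, and the cause of each change was not tested. In young pairs, against 1, there were 3 without the dye term, 14 with the young pairs fitted alone, 8 with a dye coefficient for each age, 2 after centring, 3 after scaling, 5 with all grids as a block, 14 with robust regression, 16 with array weights, 4 under the other reading (without Nppa), 7 with the dye turned in old pairs, 4 without values of 0 or at the ends, 2 of 582 single spots, and 3 without the noisiest genes, when fewer genes were tested. In old pairs, against 1, there were 6 with the old pairs fitted alone, 2 with a dye coefficient for each age, 3 with all grids as a block, 2 without the noisiest genes, 11 with robust regression, 2 with array weights, 2 without values of 0 or at the ends, and 2 of 582 single spots, while the other reading gave 1 that was not Nppa. In the mean of both ages, against 12, there were 2 on grid 2 alone, 24 with robust regression (10 of the 12 among them), 4 without old pair 1 and young pair 5, 19 of 582 single spots, and 0 under the other reading (14 at an unadjusted p under 0.05 in limma). A dye coefficient for each age gave 17 genes in the mean, 11 positive and 6 negative. Centring gave 14 genes, 11 of the 12 among them, of which 8 were positive, and scaling gave 16, of which 8 were positive, so the share on the positive side went from 75% to 57.1% and 50.0%. For the difference between ages, against 0, the other reading gave 21, and a block on pair number gave 0 (4 at an unadjusted p under 0.05). Over genes, the deviations of pairs of the same number at different ages, which also share the dye orientation, correlated with r = −0.15, −0.22, −0.072 and −0.27. Pairs of different numbers with the same orientation had r from −0.30 to 0.089, so these values do not show whether the numbers pair the mice.

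Leaving out 1 pair at a time, which means fewer samples, the count ran from 1 to 4 in young pairs (2 without young pair 1, 2 without old pair 1, 4 without old pair 3 and 3 without old pair 4). In old pairs it ran from 0 to 3 (2 without young pair 4, 0 without old pair 2, with 21 at an unadjusted p under 0.05, 3 without old pair 3, namely Nppa, Il10 and Abcb11, and 2 without old pair 4). In the mean it ran from 3 to 12 (3 without young pair 3, 5 without old pair 1 and 6 without old pair 2), and for the difference from 0 to 2 (2 without old pair 3, Il10 and Abcb11). Lists past the threshold in young pairs, against 2, were 0 with an estimated correlation (0 at an unadjusted p under 0.05), 0 in fry (4 at an unadjusted p under 0.05), 1 without the dye term, and 0 to 2 leaving out 1 pair (0 without young pair 1, 3 or 4, 1 without young pair 2). In old pairs they ran from 0 to 1 (1 without old pair 2), in the mean from 0 to 1 (1 without young pair 5) with 2 after centring, and for the difference they were 0 throughout, with 1 at an unadjusted p under 0.05 by camera and 0 by fry.

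Under the other reading 37 values changed sign, 8 of them of called results. In the mean of both ages these were Nppa (−0.39), Slc38a2 (−0.040), Ctsh (−0.098), Slc38a4 (−0.043), Fn1 (−0.12), Ankrd1 (−0.19), Slc38a3 (0.0067), Csad (−0.056), Myh7 (−0.13), Ryr2 (−0.10), Pln (0.018), Xbp1 (−0.030), G6pc (−0.024), Fas (−0.10), Timp2 (−0.19), Il1r1 (−0.073), Jun (0.12), Prkg1 (−0.24), Ctsb (−0.090), Kdr (0.0029), Col1a2 (−0.13) and Mb (0.20). In young pairs they were Nppa (−0.17), Angpt1 (−0.032), Slc38a2 (−0.22), Ankrd1 (−0.067), Acta1 (0.12), Slc38a3 (0.27), Timp2 (−0.15) and Fn1 (−0.15), in old pairs Nppa (−0.61), Abcc6 (−0.18) and Etfdh (0.070), and for the difference Abcc2 (−0.37), Nme1 (−0.28), Aqp9 (−0.82) and Slc6a6 (−0.18). The cause lies in the construction, which turns the sign of the 4 pairs with the knockout heart in Cy3.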

Other observations

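All tests in this part were chosen only after the results were seen.

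Beyond the lists fixed beforehand, 20 genes for mitochondrial proteins of several pathways were picked by their known location, among them the beta-oxidation enzymes Hadha and Hadhb, the chaperonins Hspd1 and Hspe1 and 3 mitochondrial ribosomal proteins. On average over both ages 16 of the 20 had a negative ratio (17 after centring), with a mean of −0.16 and 1 call, Etfdh. A hypothesis is that transcripts of mitochondrial proteins shifted together against other genes, on the side of Acta1 and opposite to Nppa. Camera gave an unadjusted p of 8.66e-05 with the preset correlation and 0.160 with an estimated correlation, so such a shift may exist, but the correlation between the genes leaves it undecided.

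For cyclic GMP signalling 4 measured genes were picked. They were Npr1, the receptor of atrial natriuretic peptide, Gucy1a1 and Gucy1b1, subunits of the soluble guanylate cyclase that nitric oxide activates, and the kinase Prkg1. All 4 had a positive fitted ratio at both ages, on the side of Nppa, with a mean of 0.34 over both ages and no call of a single gene. Not among the 4 were the phosphodiesterase Pde3a (0.010 in the mean of both ages) and the nitric oxide synthases Nos1 (0.12), Nos2 (−0.25) and Nos3 (0.036), which were measured too. The grids disagreed for Npr1, which had 0.59 on grid 1 alone and 0.079 on grid 2 alone in the mean of both ages. Old pair 4 went the other way, with 3 of the 4 negative and a mean of −0.36 after the array's median was taken off. A hypothesis is that the 4 picked genes shifted together against other genes. Camera gave an unadjusted p of 0.0110 with the preset correlation and 0.0895 with an estimated correlation, so the data may carry such a shift but do not settle it.

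Over 20 families of at least 3 genes that share the first 3 letters of their symbol, the ABC family was the only one past camera's threshold in old pairs (adjusted p = 0.0228), and with an estimated correlation it was not (adjusted p = 0.905). The 17 solute carriers averaged 0.015 over both ages, with Slc38a2, Slc38a4 and Slc6a6 called, so the positive ratios of these 3 were not shared by the family. The 2 probes for Casp8 differed, at −0.061 and 0.38 in the mean of the pairs.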
